A study of Homo sapiens with 2 samples.

How the data were processed

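Total RNA from 2 cultures of TIME cells was measured on single-colour oligonucleotide arrays. TIME cells are human microvascular endothelial cells immortalized with telomerase, an established line. One culture had been transduced with a lentivirus carrying human JunB cDNA and the other with the empty vector, per the labels' protocols. Biotin-labelled cRNA was made from 100 ng of total RNA with a whole-transcript kit, per the labels' protocols, so a value summarises probes along a gene and not only at its 3′ end. Each group held 1 array. There was no replicate error for any difference, and no p-value was computed.

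The authors deposited 1 intensity per transcript cluster on a linear scale, which is a brightness in arbitrary units. The signals were made with Affymetrix Expression Console, per the submitters' processing notes. Its version, the background correction, the summarisation, the normalization and the genome build are not given in the sources used here. The quartiles of both arrays were nearly equal (50.3, 127.5 and 489.5 with the control vector, 50.3, 127.6 and 489.5 with the JunB vector). This points to arrays brought to a common distribution before deposit, though no such step is given. A change in total RNA per cell would not be seen, since 100 ng was labelled for each array. No value was below 18.7, which leaves open an added constant that would shrink the differences of dim genes. No detection calls were used here, and the depth of an array has no count equivalent, so the number of arrays limits the precision.

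The table held 28869 transcript clusters. A platform annotation gave 1 gene symbol to 19310 of them, several to 1752 and none to 7807. Symbols were updated through the Entrez ID in a RefSeq gene table (GRCh38.p14), which held 19279 of the 19310. The table served only for names and for the order of genes along chromosomes, and no coordinates are given because the build behind the array values is not known. Transcript clusters with several symbols or none were left out of gene results. A gene with several clusters (685 genes) took the cluster with the highest mean of the 2 arrays, which gave 18377 genes.

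Signals were taken to log2 as deposited, with no pseudocount. The difference was JunB vector minus control vector. A gene counted as measured when the higher of its 2 signals was at or above 207.0, the median of all values with 1 symbol. This brightness filter kept 9398 genes. Genes were counted by size at 2-fold. Gene lists were written before the data were examined, as were the rule for named genes and all alternatives except those named below as added later. The median difference of each list was set among the medians of 10000 random lists of the same size, drawn from 20 bins of mean signal to match the list. A percentile under 2.5 or over 97.5 was called outside the random range, as a description of these 2 arrays. Lists with fewer than 5 measured genes got no percentile. Genes of a list are regulated together, which the random lists ignore.

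The genes named are JUNB, up to 12 per direction with the largest differences of at least 2-fold, and up to 4 measured members per list with the largest absolute differences. Small RNAs and genes known only by a locus, open reading frame or family number were to be counted and not named. Other genes are marked where they were chosen after their values were seen.

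The procedure was tested on simulated data with the signals of these 18377 genes and independent noise. The noise was normal, with a spread per bin of signal taken from the median absolute deviation between these 2 arrays. Of 50 genes raised by 1.5 on the log2 scale, 50 passed the 2-fold size, as did 0 of 50 raised by 0.5 and 0 of 9198 unchanged genes. Noise this narrow nearly fixes all these counts in advance, so they are no rates of detection or of false calls. Outlying genes and variation between cultures were not simulated. Of 100 unchanged random lists of 20 genes, 7 fell outside the random range. Of 100 lists shifted by 0.1, 91 lay above it.

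The alternatives were centring the differences, quantile normalization of the 2 arrays, removal of a loess trend (span 0.3), the mean of all clusters of a gene, no brightness filter, a stricter filter at 668.2, size thresholds of 1.5-fold and 3-fold, list means in place of medians, and random lists not matched on signal. Subtracting 16 from each value before log2, a brightness filter on the mean of both arrays at the same floor, and raising every signal below the floor to it, were chosen after seeing the data. The main filter takes the brighter array, so a gene can pass through 1 array alone. For such genes among those named, the fold or difference is given against the floor, as a lower bound on its size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.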

Results

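Gene expression was compared between TIME cells transduced with a JunB expression vector and TIME cells transduced with an empty vector, to find which transcripts differ when JunB is overexpressed in microvascular endothelial cells. JunB is a member of the AP-1 family of transcription factors. Each condition was measured on 1 array, so every difference below compares these 2 arrays and carries no replicate error. Of 18377 genes with a value, 9398 were bright enough on at least 1 array to count as measured. The log2 signals of the 2 arrays correlated across all 18377 genes (Pearson r = 0.996), though genes are not independent replicates. Of the measured genes, 85.8% differed by less than 0.2 on the log2 scale.

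JUNB itself had a signal of 503.7 with the control vector and 2782 with the JunB vector, a 5.52-fold difference that goes with the labels. In all, 29 genes were at least 2-fold higher with the JunB vector and 11 were at least 2-fold lower, together 0.426% of the measured genes. At 1.5-fold the counts were 74 and 52. Without replicates the spread between genes of like brightness was the only yardstick. In 5 bands of mean signal the SD of the log2 difference over genes was 0.138, 0.162, 0.190, 0.194 and 0.173 from the dimmest to the brightest. For 209 genes with 2 transcript clusters, both at or above 207.0 on both arrays, the 2 differences correlated at r = 0.720 across genes. They differed with an SD of 0.0902. Both clusters read the same RNA on the same arrays, so their agreement says nothing on variation between cultures.

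The 12 largest increases by deposited value, JUNB included, divide by whether the control signal reached the brightness floor of 207.0. Among those bright on both arrays, LRRC38, an auxiliary subunit of large-conductance potassium channels, was 9.29-fold higher, and the sulfotransferase SULT1B1 was 6.62-fold higher. The orphan receptor GPRC5B was 5.22-fold higher, the neutrophil chemokine CXCL8 4.83-fold and the cytokine IL1A 3.11-fold. For the other 6 the control signal lay below the floor, and the fold is given as a lower bound against the floor, which leaves them without an order. AMTN, which encodes the enamel matrix protein amelotin, had signals of 105.6 and 1636 and was at least 7.90-fold higher. The homeobox gene HOXB9 (signals of 141.2 and 484.9) was at least 2.34-fold higher, CXCL12, the ligand of the receptor CXCR4 (122.6 and 447.7), at least 2.16-fold and the transporter SLC16A9 (132.8 and 418.2) at least 2.02-fold. The inflammatory cytokine IL1B (65.9 and 413.3) was at least 1.997-fold higher and PLCXD3 (65.1 and 325.9) at least 1.57-fold, both under 2-fold at this bound. With all signals below the floor raised to it, which was chosen after seeing the data, 22 of the 29 genes stayed at least 2-fold higher and 10 of the 11 at least 2-fold lower.

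**Figure D1:**
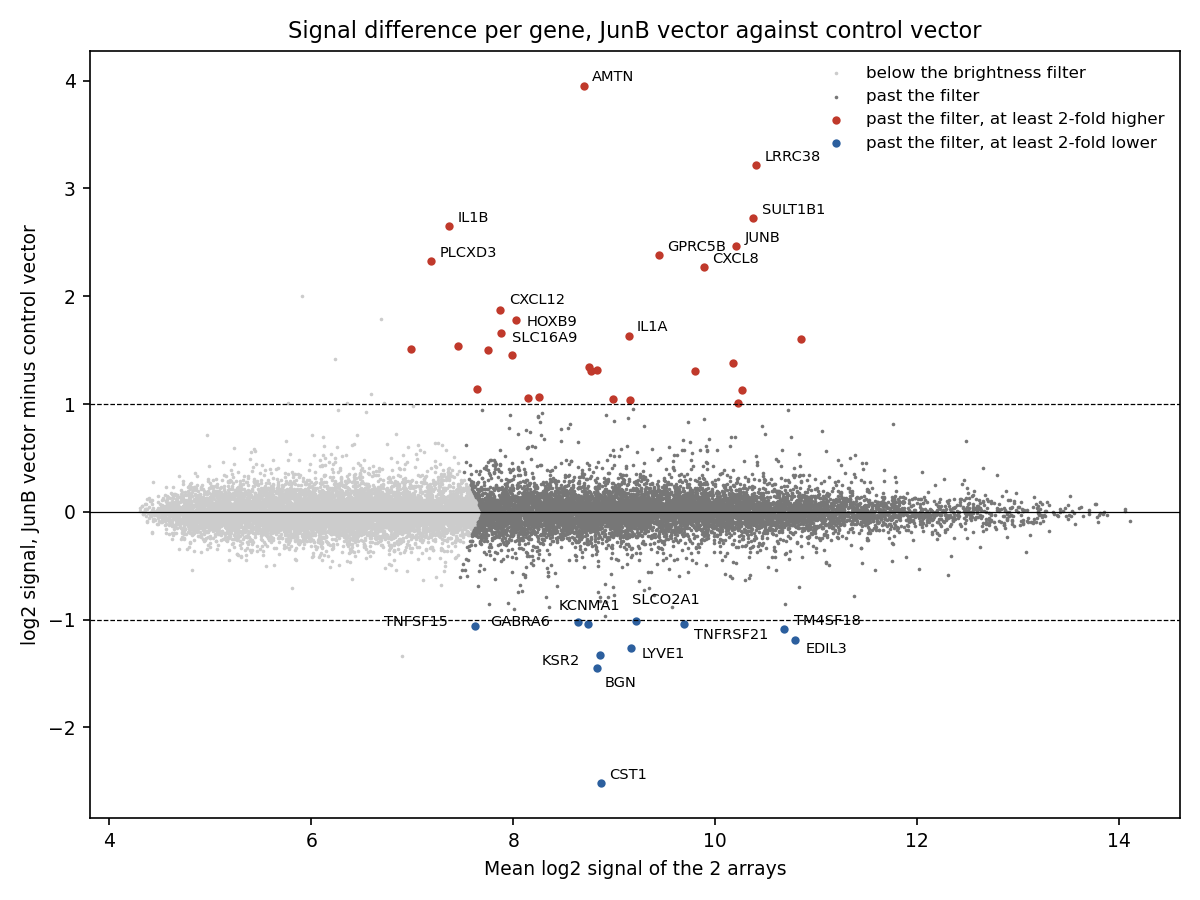
Each point is a gene, with the mean log2 signal of the 2 arrays on the horizontal axis and the log2 difference, JunB vector minus control vector, on the vertical axis. Red points are the 29 genes at least 2-fold higher and blue points the 11 at least 2-fold lower, light grey points lie below the brightness filter, dashed lines mark 2-fold, and JUNB stands at 2.47.

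Among the 11 genes at least 2-fold lower, CST1, a secreted inhibitor of cysteine proteases, had the largest difference. Its signal was 1117 with the control vector and 195.5 with the JunB vector, which lies below the floor, so it was at least 5.40-fold lower. Its close relatives CST2 and CST4, chosen after their values were seen, had signals of 241.8 and 171.4, the second below the floor, and of 275.3 and 281.2. The proteoglycan gene BGN was 2.74-fold lower, the kinase scaffold KSR2 2.504-fold, the lymphatic hyaluronan receptor LYVE1 2.40-fold and EDIL3, which encodes an integrin ligand, 2.29-fold. TM4SF18 was 2.13-fold lower. TNFSF15, a cytokine of the tumour necrosis factor family, had signals of 284.5 and 136.9 and was at least 1.37-fold lower. KCNMA1, the pore-forming subunit of the large-conductance potassium channel, was 2.06-fold lower. The death receptor TNFRSF21 was 2.06-fold lower, GABRA6, a subunit of a neurotransmitter receptor, 2.03-fold, and the prostaglandin transporter SLCO2A1 2.02-fold.

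Of the 29 higher genes, 4 lay in 1 stretch of a chromosome, though only CXCL8 and CXCL1 were close together. In the order of genes in the RefSeq annotation, SULT1B1, AMTN, CXCL8 and CXCL1 lay within a stretch of 37 genes with a value. CXCL1, a chemokine related to CXCL8, was 2.02-fold higher. The gene next to SULT1B1, the related SULT1E1, stayed below the brightness floor and had signals of 29.9 and 120.0. The 7 other genes of the stretch that were bright enough, among them UTP3, GRSF1, DCK and ANKRD17, had a median log2 difference of 0.01 and a range from -0.07 to 0.15. The remaining 25 genes were dim on both arrays, and this stretch was chosen after the values were seen.

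**Figure D2:**
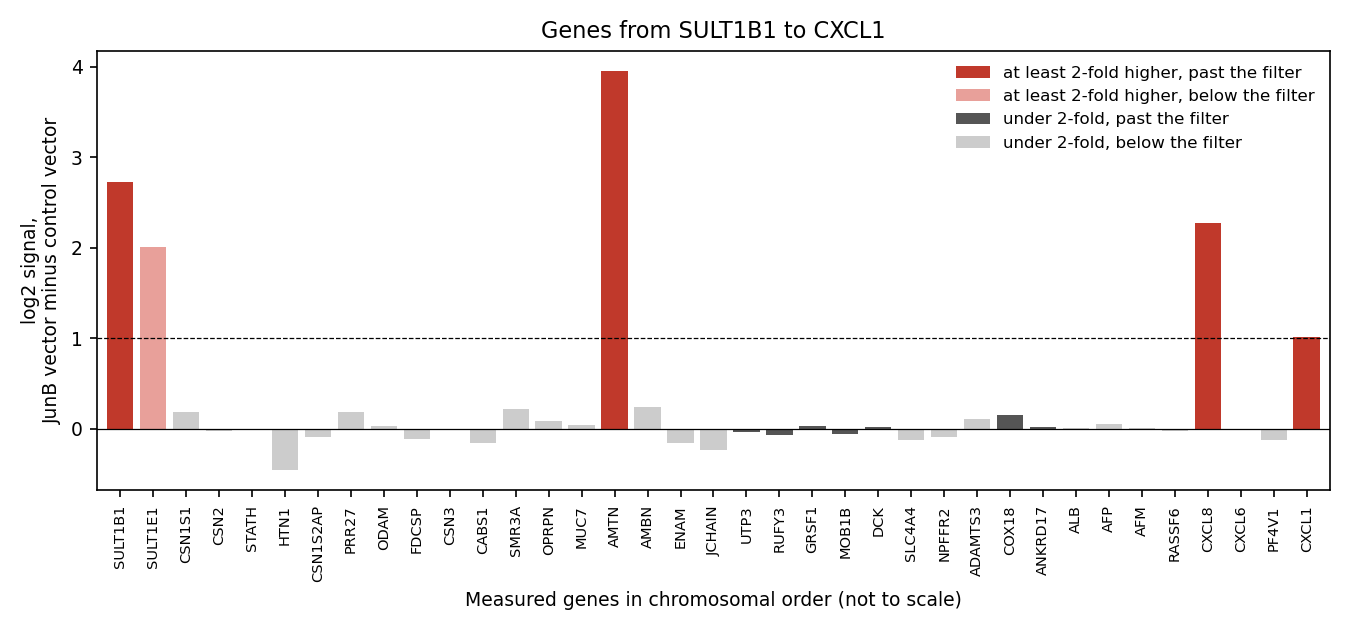
Bars give the log2 signal difference, JunB vector minus control vector, of the 37 genes with a value from SULT1B1 to CXCL1 in chromosomal order, with distances not to scale. Red bars are the 4 genes at least 2-fold higher that passed the brightness filter, the pale red bar is SULT1E1, dark grey bars are other genes past the filter, light grey bars are dim genes, and the dashed line marks 2-fold.

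A set of cytokine and chemokine genes was higher with the JunB vector. Of 9 measured members, 5 were at least 2-fold higher (IL1B, CXCL8, CXCL12, IL1A and CXCL1), 0 were at least 2-fold lower and 4 differed by less than 2-fold. The list median was 1.01 on the log2 scale, at percentile 100 of the random lists. This size depends on which genes count as bright, since IL1B and CXCL12 passed only through the JunB array. With both at their bound the median was 0.997 and IL1B fell just under 2-fold. With the filter on the mean of both arrays, chosen after seeing the data, the median of 8 members was 0.79, and with no filter the median of 27 members was 0.078 (percentile 99.73). The list of NF-kB feedback genes and leukocyte adhesion molecules, which hold common targets of inflammatory signalling, had 0 of 10 members at 2-fold. Its median was -0.04 (percentile 21.8), with TNFAIP2 at 0.22, NFKBIA at 0.19, ICAM1 at 0.18 and RELB at -0.12. Of 13 measured interferon-stimulated genes, 12 lay above 0 and 0 reached 2-fold, with a median of 0.10 (percentile 99.25). IFIT5 was at 0.48, SAMD9 at 0.32, IFI35 at 0.26 and OAS3 at 0.24. With no filter 26 of 31 interferon-stimulated genes lay above 0, with a median of 0.10 (percentile 100), though the added members were dim. With the stricter brightness filter only 5 interferon-stimulated genes were left and the percentile was 95.26, inside the random range.

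Endothelial markers were mostly lower with the JunB vector, by small amounts. Of 22 measured pan-endothelial markers, 17 lay below 0 and 5 above, and 0 reached 2-fold. Their median was -0.13, a level of 0.911 relative to the control vector (percentile 0). The matrix glycoprotein gene MMRN1 was at -0.96, EGFL7 at -0.43, CLEC14A at -0.37 and ICAM2 at -0.32. Of 6 measured lymphatic markers, 5 lay below 0, and the median was -0.50 (percentile 0). With no filter the median of 14 members was -0.18 (percentile 0), and with signals below the floor raised to it the median of the 6 was -0.38 (percentile 0). LYVE1 was at -1.26, TFF3 at -0.61 and RELN at -0.56, while PDPN, which encodes podoplanin, was at 0.45. PROX1, the master regulator of lymphatic identity, was too dim to count on either array.

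Markers of endothelial tip cells, the leading cells of a vascular sprout, went in both directions. Of 16 measured, 11 lay below 0 and 5 above, 0 reached 2-fold, and the median was -0.11 (percentile 0.08). ANGPT2, a ligand that destabilizes vessels, was 1.82-fold higher (0.86). The peptide hormone gene APLN was at -0.78, the semaphorin and VEGF receptor NRP2 at -0.49 and CXCR4 at -0.47. The 11 measured stalk cell and Notch pathway genes had a median of 0.01 (percentile 61.465), with JAG2 at -0.40, MFNG at -0.38, NOTCH1 at -0.33 and HES1 at 0.29. The 7 measured arterial and venous markers had a median of -0.11 (percentile 1.47) but a mean of 0.01 (percentile 61.89). EFNB2, an arterial ephrin, was at 0.85, while NRP2 was at -0.49, ACVRL1 at -0.24 and NRP1 at -0.16.

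The lists of markers of other cell types also had medians below 0. Of 9 measured epithelial and keratinocyte markers, 9 lay below 0, with a median of -0.22 (percentile 0), or -0.090 over 21 members with no filter (percentile 0.3). All 9 were bright with the control vector, among them KRT7 (signal 5376) and PERP (3218), whereas EPCAM, CDH1 and KRT5 were dim on both arrays. The median of the 9 thus describes genes that these cultures express, and does not show a change in epithelial cells. LAMB3 was at -0.88, CLDN1, with its dim JunB signal raised to the floor, at -0.43, CLDN7 at -0.39 and JUP at -0.25. The 6 measured fibroblast and mural cell markers had a median of -0.10 (percentile 3.16), or -0.046 over 23 members with no filter (percentile 8.48). The 6 were also bright with the control vector. SNAI2, a transcription factor of mesenchymal transition, was 1.75-fold higher (0.81), whereas the smooth muscle genes TAGLN and ACTA2 were at -0.49 and -0.45 and MCAM was at -0.12. CD68, at -0.24, was the only leukocyte marker bright enough to count, and its signal was already 2083 with the control vector.

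The list of matrix genes had a median below 0 and that of integrins a median above 0. Of 23 measured basement membrane and matrix genes, 14 lay below 0 and 9 above, and 1, BGN, was at least 2-fold lower. The median was -0.07 (percentile 1.21, or 2.67 and inside the random range with the stricter filter). LAMB3 was at -0.88 and COL8A1 at -0.69, while TGFBI, which encodes a secreted adhesion protein, was at 0.66. Of 11 measured integrin genes, 9 lay above 0 and 2 below, with a median of 0.13 (percentile 99.94), or 0.073 over 18 members with no filter (percentile 99.2). ITGB3 was at 0.61, ITGB8 at 0.49, ITGA10 at 0.20 and ITGA6 at -0.35. The 13 measured matrix proteases and inhibitors had a median of 0.00 (percentile 62.195), with ADAM19 at 0.65, PLAT at 0.45, PLAU at -0.54 and ADAMTS9 at -0.51. The 12 measured junction genes had a median of 0.01 (percentile 67.08), with CDH2 at 0.52 and CLDN11 at -0.59, and, with the dim signal of each raised to the floor, MARVELD2 at 0.33 and CLDN1 at -0.43.

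Axon guidance genes, many of which also guide vessels, included large differences of both signs. Of 22 measured, 13 lay below 0 and 9 above, and 0 reached 2-fold. EFNB2 was at 0.85, SEMA3C at 0.77, SEMA7A at 0.76 and PLXNA4 at -0.77. The median was -0.09 (percentile 0.13), or -0.051 over 34 members with no filter (percentile 1.78), and the mean of -0.02 lay inside the random range (percentile 24.87). Of 22 measured neurotrophic and angiogenic growth factors, 12 lay below 0 and 10 above. ANGPT2 was at 0.86, FGF2 at 0.82, ANGPTL4 at 0.58 and TGFB2 at -0.79. The median was -0.07 (percentile 0.84), the mean 0.06 (percentile 90.43), and the median with the stricter filter 0.0095 (percentile 58.02), so the list had no settled direction.

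Genes of DNA replication were higher and genes of mitosis lower, by small amounts. Of 28 measured replication genes, 25 lay above 0, with a median of 0.14 (percentile 100). MCM10 was at 0.34, CDC6 at 0.31, POLE2 at 0.30 and RFC4 at 0.29. Of 29 measured mitosis genes, 28 lay below 0, with a median of -0.12 (percentile 0). KIF20A was at -0.33, CCNB1 at -0.20, NUF2 at -0.20 and CENPF at -0.19. Of 20 measured replication-dependent histone genes, 17 lay above 0. Their median was 0.08 (percentile 99.82) and their mean 0.06 (percentile 93.04, inside the random range). H2BC3 was at 0.26, H3C12 at 0.25, H2AC13 at -0.32 and H4C5 at -0.23, and the array may not separate these near-identical genes.

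Of 20 measured p53 targets, 16 lay below 0, 3 above and 1 at 0, with a median of -0.17 (percentile 0). PLK2 was at -0.47, SESN1 at -0.34, GDF15 at -0.30 and ZMAT3 at -0.29. The 10 measured D-type cyclins, their kinases and inhibitors had a median of -0.05 (percentile 11.62), or 0.0071 over 12 members with no filter (percentile 58.94). CDK6 was at 0.27, CCND2 at 0.18, CCND1 at -0.26 and CDKN1A at -0.21. The 8 measured AP-1 genes had a median of 0.0044 (percentile 51.76). Beside JUNB at 2.47, JUN was at -0.47, FOSL1 at -0.32 and JUND at 0.07. The 19 measured genes of the joint list of MAPK feedback and immediate early genes had a median of 0.06 (percentile 96.785). Their mean was -0.04 (percentile 14.53). Of them 10 lay above 0 and 9 below, with SPRED2 at 0.57, KLF4 at 0.42 and DUSP4 at -0.64. DUSP10 had signals of 221.6 and 152.6, the second below the floor, which leaves -0.098 at the floor. With the stricter filter the median of this list was -0.10 (percentile 0.56), so the list had no settled direction.

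Cholesterol synthesis genes were mostly higher with the JunB vector, by small amounts. Of 17 measured, 15 lay above 0, 2 below and 0 reached 2-fold, with a median of 0.20 (percentile 100). The pathway enzymes MVD, LSS, SQLE and IDI1 were at 0.45, 0.39, 0.36 and 0.34. Of 21 measured genes of the unfolded protein and amino acid stress response, 19 lay above 0, with a median of 0.09 (percentile 99.93, or 96.98 and inside the random range with the stricter filter). VLDLR was at 0.46, DDIT3 at 0.44, SLC7A5 at 0.30 and SDF2L1 at 0.25. The 22 measured hypoxia genes had a median of -0.01 (percentile 40.22), with ANGPTL4 at 0.58, VEGFA at 0.44, PFKFB3 at -0.27 and ADM at -0.25. The 26 measured ribosomal protein genes had a median of -0.04 (percentile 9.21), with RPL23 at 0.19, RPL10A at 0.15, RPS23 at -0.13 and RPL13 at -0.24.

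In total, 7 of the 27 lists with a percentile lay above the random range, 10 below it and 10 inside it. Independent genes would put 1.35 lists outside. Among 105 families of measured genes that share a symbol stem, which were chosen with no regard to pathway, 7 lay outside (6.67%). The lists share 27 measured genes, and their members are regulated together, so the lists are not independent of one another. Among the 27 lists with the main filter, the epithelial markers at -0.22 were the farthest from 0 after the cytokines and the lymphatic markers. This order depends on the filter: with none, the epithelial median was -0.090 and the cholesterol synthesis genes, at 0.20, were farthest from 0. With 1 culture per condition a difference between cultures and an effect of JunB cannot be told apart.

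**Figure D3:**
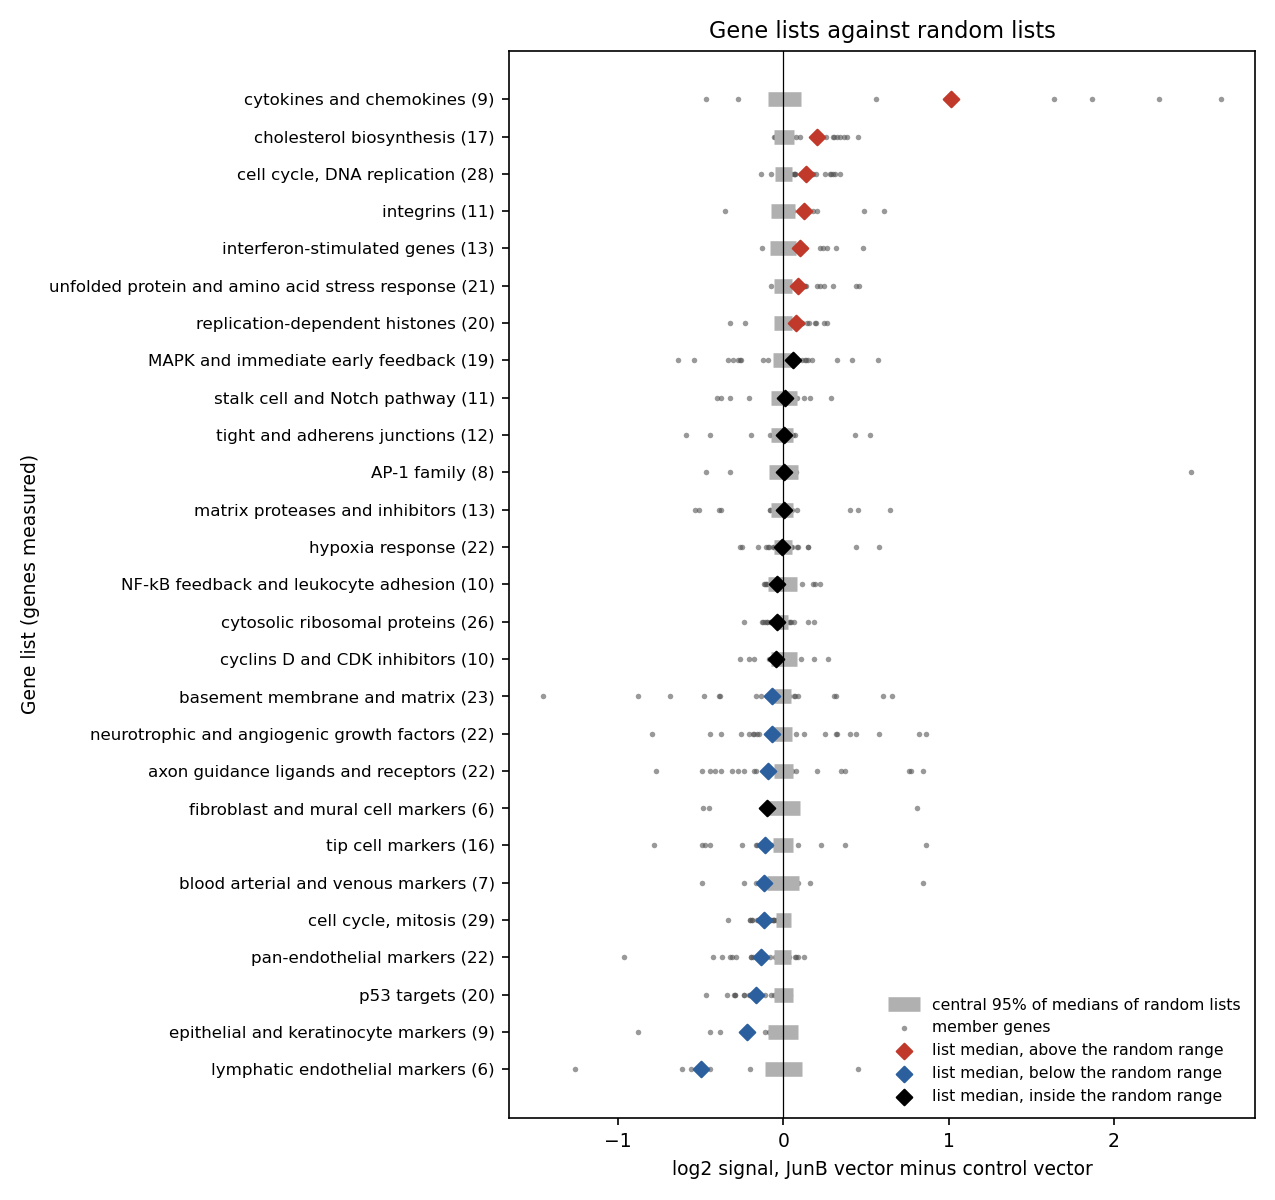
Each row is a gene list, with the number of measured genes in parentheses, and the horizontal axis is the log2 signal difference, JunB vector minus control vector. Grey bars span the central 95% of medians of 10000 random lists matched on signal, dots are member genes and diamonds list medians, with cytokines and chemokines at 1.01 and lymphatic markers at -0.50 farthest from 0.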

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

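The signals in this part come from genes and transcript clusters left out of the comparisons, and the genes were chosen after their values were seen. Below the brightness filter, 7 genes were at least 2-fold higher with the JunB vector: SULT1E1 (signals of 29.9 and 120.0), the phosphodiesterase gene PDE1C (55.5 and 191.3), DHRS9 (46.0 and 123.1), the pattern recognition receptor gene TLR2 (65.9 and 140.5), the mesenchymal transcription factor gene PRRX1 (74.2 and 149.5), CHRNA9 (57.7 and 116.2) and the hyaluronan synthase gene HAS2 (38.4 and 77.3). All these signals lie below the brightness floor of 207.0, so no exact fold is given. Here 2-fold is a ratio of deposited values and not a bound against the floor. Below the filter, 1 gene was at least 2-fold lower, the endothelial sialomucin gene EMCN, with signals of 189.8 and 75.2. Of the transcript clusters without a single gene symbol, 1 was at least 2-fold higher, with signals of 34.9 and 74.4. No biological explanation was tested for these dim signals.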

How the results depend on the processing

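No paired analysis was possible because each group holds 1 array, and no replicate could be left out. Some settings could not move single genes: the median difference was already 0 before centring, a brightness filter leaves a gene's difference as it is, and only 2 of the 118 named genes other than JUNB have several transcript clusters to average. Quantile normalization, removal of a loess trend and an offset of 16 (chosen after seeing the data) could move them, and the 118 kept their direction and their side of 2-fold under each, though the first 2 changed the values little. JUNB ranged from 2.46 to 2.504. The 29 higher and 11 lower genes passed 2-fold again under these 3 settings, and the offset raised the higher count to 30. With the filter on the mean of both arrays, also chosen after seeing the data, 24 and 10 were left. With signals below the floor raised to it, likewise chosen later, 22 and 10 were left, and IL1B (0.997), PLCXD3 (0.65) and TNFSF15 (-0.46) fell under 2-fold. The count of higher genes was 17 with the stricter filter, which tests fewer genes. It was 74 at 1.5-fold and 13 at 3-fold, and the count of lower genes was 52 and 1 at these sizes. For lists, the size of a median depends on the filter: with no filter the cytokines were at 0.078 and the lymphatic markers at -0.18. The stricter filter turned the median of the growth factors to 0.0095 and that of the MAPK feedback and immediate early genes to -0.10. Besides the growth factors, it brought 3 lists inside the random range at medians of -0.067 (basement membrane and matrix), 0.104 (interferon-stimulated genes) and 0.058 (unfolded protein and amino acid stress). Without a filter the arterial and venous median was -0.039 and the growth factor median -0.042, both inside the range. The median of the MAPK feedback and immediate early genes, 0.059, moved outside it. Quantile normalization put the growth factors at -0.054, inside the range. With means in place of medians, the arterial and venous list turned to 0.012 and the growth factors to 0.055, axon guidance (-0.020) and histones (0.058) came inside the range, and the AP-1 family moved above it at 0.22, a mean that holds JUNB at 2.47. For the other list changes the cause was not tested. In 8 lists the median and mean differ in sign. With 1 array per group, the culture and the vector cannot be separated.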

Other observations

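The gene lists were fixed before the data were examined. The scan of symbol families and the tests of each explanation below (chromosomal crowding, extra copies, related chemokines, other cell types, signal bands, lymphatic range, proliferation and S phase) were chosen after the results were seen. In the scan, 7 of 105 families lay outside the random range where 5% would by chance, so single families may be chance, and an unchanged simulation put 7 of 100 lists outside. The collagens had the lowest percentile (0.03): 12 of 12 measured lay below 0, with a median of -0.15, COL8A1 at -0.69, COL5A1 at -0.39 and COL13A1 at -0.38. The KLF genes, zinc finger transcription factors, had the highest (99.82): 12 of 13 lay above 0, with a median of 0.12 and KLF4 at 0.42. The others outside were MCM (99.8), which overlaps the replication list, CEP (98.21), MT (2.45), KCTD (1.935) and CD (1.71).

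Of the 29 genes at least 2-fold higher, 4 lie from SULT1B1 to CXCL1. Extra copies of the whole stretch would raise its other genes too, and the median of the 7 bright ones was 0.014 where 3 copies in place of 2 would give 0.58, so a gain of the whole stretch is argued against. Chance placement stays open, since the answer depends on the window and on relatives: of 10000 random draws, 5847 had as many (2 genes) within 20 genes with a value, 15 as many (4) within 40, 71 (4) within 80 and 435 (4) within 160, but with tandem relatives counted once 5417 (2 genes), 361 (3), 1336 (3) and 342 (4). Probes that read related chemokine transcripts stay open too: CXCL6, CXCL5, CXCL3 and CXCL2 had a median difference of 0.0090, but all were dim. This median hides CXCL2, which was higher, with signals of 142.6 and 203.3, the second just under the floor. All stayed far below the JunB signals of CXCL8 (2082) and CXCL1 (1706). Shared regulation of separate genes under JunB is a hypothesis that these 2 arrays cannot test.

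The lower endothelial markers may reflect a change in the cells or in the mix of cells. The medians of 5 signal bands lay within 0.0064 of 0, against -0.13 for the pan-endothelial list. The deposited values thus hold no trend with signal of that size. Near-equal distributions of the 2 arrays nearly fix such medians in advance, so they are no separate test. Other cells mixed in stay open. The highest median among the fibroblast and mural, epithelial and leukocyte lists, dim members included, was -0.0078. Above 0 were 7 of 23 fibroblast and mural, 4 of 21 epithelial and 6 of 14 leukocyte members. The medians give these types no support, but most members were dim. The fibroblast and mural (percentile 8.48) and leukocyte medians lay inside the random range. In the fibroblast and mural list SNAI2, bright on both arrays, was at 0.81 and the dim COL6A3 at 0.39. COL1A1, COL1A2, COL3A1 and LUM of that list, all dim, were at -0.12, -0.03, -0.03 and -0.16, and DCN, also dim, at 0.10. Outside that list, the matrix gene POSTN (signals of 35.7 and 52.8) and the mesenchymal factor gene PRRX1 (74.2 and 149.5) were higher. POSTN and PRRX1 were dim on both arrays, and all the dim genes named here were chosen after their values were seen. A smaller share of lymphatic-type cells stays open, since the lymphatic markers spread over 1.72 log2 units, with LYVE1 lowest and PDPN above 0, and PROX1 was too dim to decide. Lower expression per cell under JunB was not tested.

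Replication genes were higher and mitosis genes lower. A general difference in proliferation would move both lists one way, and their medians lay 0.26 apart on opposite sides of the random range. These medians are the pattern itself, so they are no separate test of it. The medians of 5 signal bands lay within 0.0064 of 0, so the deposited values hold no trend with signal of this size. Near-equal distributions of the arrays nearly fix these band medians in advance. A larger share of cells in S phase is consistent with the histone median of 0.078, above the random range, though the mean of that list lay inside it. Whether such a shift comes from JunB or from the state of 1 culture at harvest cannot be told apart.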
